A study of Homo sapiens with 4 samples.

How the data were processed

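RNA of the human lung cancer line H1299 and of its DDX21 knockout derivative was profiled in 4 libraries, 1 per group: each line was measured non-treated and after transfection with a miR-34a mimic. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into stranded libraries, so RNAs without a poly(A) tail, such as histone mRNAs and small structural RNAs, were kept. The submitters' processing notes name Bowtie2 2.0.6, TopHat2 2.0.9 and build GRCh38. The counting tool is not given in the sources used here, nor is it stated whether the counting used strand.

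The main measure was the authors' table of estimated counts per gene, deposited as whole numbers under NCBI gene identifiers, per the file headers. The deposited FPKM multiplied by transcript length was proportional to the deposited count at high counts and lay below that line at low counts, so the counts behaved as estimates rounded up to whole numbers. They were used as deposited. It was not stated whether a read pair counted as 1 or as 2, so the counting intervals could be too narrow. A 0 in such a table can also be a failed assignment to an overlapping gene. The authors also deposited FPKM per gene, which served as an alternative scale, estimated counts per transcript, and a table of their own comparisons. Per the file headers, the authors' deposited table gives for each pair of libraries a signed fold change, a raw p-value and a Benjamini-Hochberg adjusted p-value, together with adjusted p-values of gene ontology terms. The test behind these p-values is not given in the sources used here.

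The estimated counts summed to 36263145 in non-treated H1299, 32991380 in miR-34a H1299, 26868358 in non-treated DDX21 KO and 32240536 in miR-34a DDX21 KO cells. Library sizes were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors of 0.985, 0.997, 1.00 and 1.02. Levels are given as CPM, the counts scaled to the size of the library. Genes with at least 50 reads in at least 1 of the libraries compared entered a comparison. The log2 ratio was computed with a prior count of 2, and its 95% interval came from the exact Clopper-Pearson interval of the split of the reads between both libraries. A gene was called higher or lower when its ratio was at least 2-fold and the interval excluded no change. For the difference of the miR-34a ratios between the lines, the interval came from the Poisson variance of the 4 counts. These intervals cover counting error only. With 1 library per group no p-value was computed, and a call compares libraries, not conditions. Where a gene had 0 counts in a library, its fold was computed against a floor of 3 counts in that library and is written as 'at least'. This refers to the floor alone and leaves out counting error in the other library. The 95% counting interval can therefore reach lower, as for SPAG17 with miR-34a in H1299, where it began at a log2 ratio of 4.35. No bound holds if the 0 is a failed assignment.

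Markers of 5 other cell types and 39 gene lists were fixed before the data were examined, as were the rule for named genes, the comparisons and the alternative settings. Each list was summarised by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched in 10 bins of mean expression. A list was said to stand apart when its median lay outside the central 95% of those lists. Over 195 medians, 9.80 would stand apart by chance and 85 did, of which 1 is not reported here. Lists with fewer than 5 entering members were given as counts. The rule for named genes took DDX21 and its paralog DDX50, the 12 protein-coding, non-histone genes per direction and comparison whose interval bound nearest to 0 was highest or lowest, 6 per direction for the difference, the 2 highest and 2 lowest members of each described list, and 12 miR-34a targets of interest. Genes that share exons with a neighbour, or that have near-identical copies, were named as uncertain.

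Sites for miR-34a were searched in the 3' UTR of each gene's transcript with the longest 3' UTR in GENCODE 29, on GRCh38. A gene had a site when that UTR held CACTGCC or ACTGCCA, the complements of the miR-34a seed. A 3' UTR was found for 11918 of 12060 protein-coding genes that entered. The median log2 ratio of genes with a site minus that of genes with none was given with a bootstrap interval over genes, and CACTGCC was ranked among all 7-mers held by at least 100 genes by the same difference.

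The functions were tested on simulated counts drawn from the means and library sizes of each comparison, with 200 genes changed by known folds. The changed genes came only from genes whose expected count before the change lay well above the minimum of 50 in both libraries. Recovery of changes in genes nearer to that minimum or below it was not tested. For miR-34a in H1299, 13397 genes ran, 100% of the 4-fold and 36.0% and 50.0% of the 2-fold changes (higher and lower) were called, and 0 of 13197 genes simulated without change were called with Poisson noise alone. When the simulated spread between libraries was 0.2 (coefficient of variation), 251 of 13273 genes simulated without change were called. Spread between cultures could not be measured here. For miR-34a in DDX21 KO cells, 13280 genes ran with Poisson noise alone, 100% of the 4-fold changes and 58.0% and 60.0% of the 2-fold changes (higher and lower) were called, and 0 of 13080 unchanged genes, against 276 of 13111 at a spread of 0.2. For the non-treated lines, 13420 genes ran, 100% of the 4-fold and 50.0% and 54.0% of the 2-fold changes were called, and 0 of 13220 unchanged genes, against 288 of 13215 at that spread. For the lines with miR-34a, 13351 genes ran, 100% of the 4-fold and 54.0% and 38.0% of the 2-fold changes were called, and 1 of 13151 unchanged genes, against 271 of 13252 at that spread. The data held 1073, 443, 890 and 947 calls in the same order, so spread of that size could account for some of the calls in each comparison.

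Alternatives were DESeq2 1.42.0 size factors, total counts, count minimums of 10 and 200, a prior count of 0.5, the deposited FPKM with a pseudocount of 0.5, a fold threshold of 1.5, protein-coding genes scaled alone, 20 bins for the lists, Spearman's rho for the correlations, and for the seed sites 8-mers alone, any annotated 3' UTR, or site-free genes matched on UTR length and expression. Leaving out replicates and other splits of the samples do not apply with 1 library per group. The authors' list of genes behind each ontology term was not used here.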

Results

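RNA was sequenced from the human non-small cell lung cancer line H1299 and from a derivative in which DDX21 had been knocked out (DDX21 KO). DDX21 is a nucleolar DEAD-box RNA helicase that acts in the transcription and processing of ribosomal RNA. Each line was measured non-treated and after transfection with a mimic of miR-34a, a microRNA that represses cell cycle genes. Transfections used 25 nM RNA and cells were harvested after 48 h. Each of the 4 groups had 1 library, so the differences below have no replicate check and lie between libraries. The non-treated samples are not said to have received a control RNA, so the comparisons of miR-34a with non-treated cells include the transfection itself. Library totals ran from 26868358 to 36263145 estimated counts, of which 86.9% to 88.8% fell on protein-coding genes, and a floor of 3 counts corresponded to between 0.0840 and 0.111 CPM. Intervals given in brackets are 95% counting intervals of the log2 ratio. Folds written as 'at least' are computed against the floor of 3 counts and leave out counting error, so their counting intervals can reach lower.

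DDX21 mRNA was lower in both libraries of the knockout line but was still present. DDX21 (gene 9188, chromosome 10, 68956131 to 68985069 on GRCh38) stood at 722 CPM in non-treated H1299 and 588 in miR-34a H1299, against 206 in non-treated and 182 in miR-34a DDX21 KO cells. The log2 ratio of DDX21 KO to H1299 was -1.81 (-1.85 to -1.77) without miR-34a, a 3.51-fold lower level, and -1.69 (-1.73 to -1.65) with it. The transcript NM_004728 held most DDX21 reads in each library, with 24711, 18265, 5254 and 5344 counts in the same order. The edited part of the gene is not given in the sources used here, so reads cannot be placed relative to it, and an mRNA level does not test the protein. DDX50 (gene 79009), the adjacent paralog of DDX21 whose annotated transcripts overlap its start, was at 88.6, 87.6, 70.2 and 73.2 CPM, and DDX50 differed between the lines by log2 ratios of -0.34 (-0.42 to -0.25) and -0.26 (-0.34 to -0.18). With miR-34a, DDX21 itself had log2 ratios of -0.30 (-0.32 to -0.27) in H1299 and -0.18 (-0.23 to -0.12) in DDX21 KO cells.

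**Figure D1:**
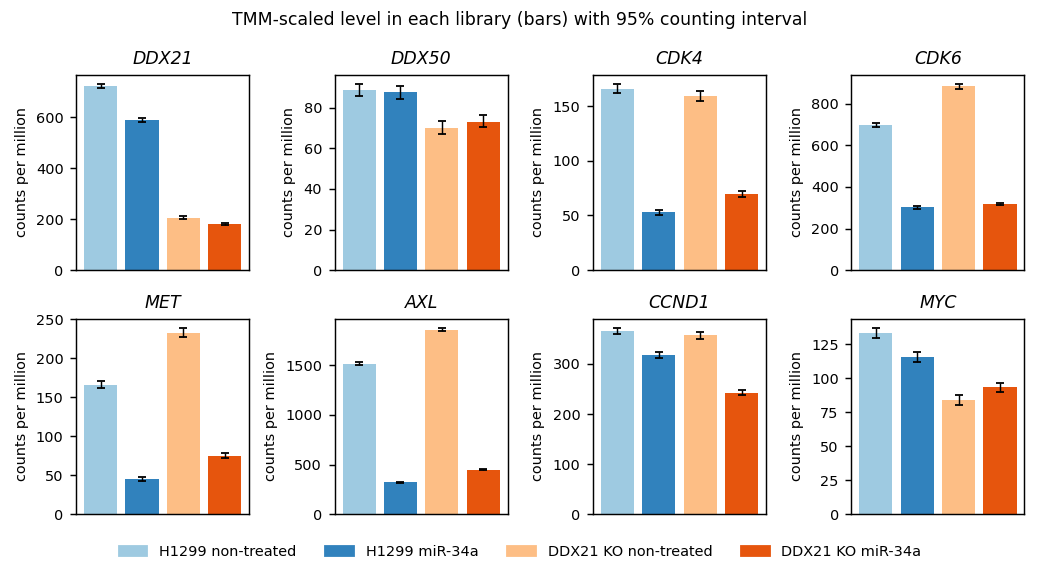
Level of DDX21, DDX50 and 6 reported miR-34a targets in each of the 4 libraries, in TMM-scaled CPM on linear axes from 0, with exact Poisson 95% intervals as error bars (1 library per bar). DDX21 lay at 722 and 588 CPM in H1299 and at 206 and 182 in DDX21 KO cells, and CDK4, CDK6, MET and AXL were lower with miR-34a in both lines.

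The first question was what the miR-34a mimic did to the transcriptome of H1299 cells. Genes of cell cycle entry, DNA replication, mitosis and histone supply were lower in the transfected library, together with reported miR-34a targets, while targets of NRF2 and NF-kB, interferon-stimulated, lysosomal and antigen presentation genes were higher. Of 13597 genes entering, 492 were higher and 581 lower by at least 2-fold. Among the reported direct targets of miR-34a, 21 of 52 were lower and 1 was higher, with a median log2 ratio of -0.78 (percentile 0). The receptor tyrosine kinase AXL (gene 558, chromosome 19, 41219223 to 41261767) stood at 1517 CPM in non-treated and 322 in transfected cells, a log2 ratio of -2.24 (-2.27 to -2.21). MET (gene 4233, chromosome 7, 116672196 to 116798386), the hepatocyte growth factor receptor, had a log2 ratio of -1.87 (-1.95 to -1.79). The G1 kinases CDK4 (gene 1019) and CDK6 (gene 1021, chromosome 7, 92604921 to 92836573) stood at -1.65 (-1.73 to -1.58) and -1.21 (-1.25 to -1.18). RRAS, a small GTPase, and TPD52 had the lowest ratios of the list, -2.27 (-2.62 to -1.98) and -2.24 (-2.35 to -2.14), and CCNE2, a cyclin of S phase entry, was at -1.15 (-1.30 to -1.02). Several well-known targets stayed within 2-fold: SIRT1 was at -0.69 (-0.79 to -0.59), E2F3 at -0.70 (-0.80 to -0.61), BCL2 at -0.96 (-1.42 to -0.56), NOTCH1 at -0.70 (-1.22 to -0.23), CCND1 at -0.20 (-0.24 to -0.16), MYC at -0.20 (-0.27 to -0.14) and JAG1 at 0.32 (0.12 to 0.52). The checkpoint ligand CD274 had the highest ratio of the list, 1.04 (0.74 to 1.37), followed by KLF4 at 0.54.

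The replication-dependent histones had the lowest median of the 39 lists in H1299, at -1.57 (percentile 0), and 55 of the 57 entering genes were lower. Their copies are near-identical in sequence, so single histone genes are uncertain; H4C9 was at -2.34 and H2AW, the highest, at -0.35. Among DNA replication genes 27 of 49 were lower and none higher, with a median of -1.04 (percentile 0). TK1, the thymidine kinase of S phase, was at -2.48 (-2.63 to -2.34) and thymidylate synthase TYMS at -1.83 (-1.93 to -1.75), while RPA2 and the histone mRNA binding protein SLBP were at -0.29 and -0.17. Of the mitotic genes 15 of 43 were lower, with a median of -0.91 (percentile 0). HMMR was at -1.78, the mitotic transcription factor FOXM1 at -1.55 and the cyclin kinase subunit CKS2 at 0.01. The G1 cyclins, kinases and their regulators had a median of -0.41 (percentile 0.01) with 7 of 22 lower, and CDKN1A and CDKN2B, inhibitors of these kinases, were both at 0.90. MYC targets (-0.36), snoRNA host genes (-0.41), box C/D and box H/ACA snoRNAs (-0.56 and -0.35), splicing factors (-0.21), tRNA synthetases and initiation factors (-0.21), stress response targets of ATF4 (-0.25), mitochondrially encoded mRNAs (-0.47) and ribosome biogenesis factors (-0.09) also stood apart on the low side. Mitochondrially encoded mRNAs, box H/ACA snoRNAs, splicing factors and ribosome biogenesis factors were low in DDX21 KO against H1299 without miR-34a too. That comparison uses the same non-treated H1299 library, and in neither comparison without it did they stand apart. These low medians therefore cannot be told apart from a deviation of that library. Targets of ATF4 stood apart only in ratios that use the miR-34a H1299 library, so the same limit holds for that library. The share of counts on rRNA genes was 0.663% in the non-treated and 0.431% in the transfected library. The box C/D median was 0.15, in the other direction, with a count minimum of 200, and with other count minimums box H/ACA snoRNAs (10 and 200) and ribosome biogenesis factors (10) no longer stood apart.

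On the high side in H1299, NF-kB targets and cytokines had a median of 0.73 (percentile 100) with 6 of 17 higher and 1 lower; the cytokine LIF was at 2.52 (2.24 to 2.85), IL32 at 1.85 (1.65 to 2.07), SOD2 at -0.48 and PTGS2 at -1.59 (-2.53 to -0.91). NRF2 targets, which answer oxidative stress, had a median of 0.71 (percentile 100) with 8 of 19 higher. ABCC3 was at 2.23 (1.69 to 3.01) and OSGIN1 at 1.99 (1.80 to 2.19), against -0.88 for AKR1C2 and -0.48 for PGD. Antigen presentation and checkpoint genes stood at 0.51, AP-1 at 0.50, interferon-stimulated genes at 0.45, lysosome and autophagy genes at 0.45, TGF-beta and YAP targets at 0.42 and MAPK/ERK output genes at 0.21, and each of these stood apart. The interferon-stimulated IFI44 had a log2 ratio of 2.95 (2.34 to 4.00) and LGALS3BP 2.31 (2.01 to 2.67), while HERC5 was at -0.47. The autophagy receptor SQSTM1 was at 1.99, and within AP-1 FOS was at 1.64 (1.24 to 2.13) and FOSL1 at -2.23 (-2.40 to -2.08). AP-1 no longer stood apart with a count minimum of 10 (median 0.26), nor did MAPK/ERK output genes with a minimum of 200 or with FPKM.

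Outside the lists, the 12 highest genes in H1299 held 4 read-through loci, which share exons with their neighbours and are uncertain (BIVM-ERCC5, MICOS10-NBL1, C8orf44-SGK3 and RPL36A-HNRNPH2). DNAH7 (gene 56171), a dynein heavy chain of motile cilia, had 57 and 567 counts and a log2 ratio of 3.39 (3.04 to 3.85), CFAP206, a radial spoke factor of the axoneme, was at 3.40 (2.90 to 4.17), and AK8 and PPP1R42 were at 3.99 (3.23 to 5.87) and 3.61 (2.83 to 5.49). SPAG17, of the axoneme's central pair, had 0 and 71 counts, at least 25.7-fold higher against the floor of 3 counts, and DCDC1 0 and 87 counts, at least 31.5-fold higher. SEPTIN5, with 0 and 80 counts, overlaps a read-through locus and is uncertain. The cytokine TNFSF15 was at 3.62 (2.99 to 4.82). Of the 12 lowest genes, FSBP, which lies within RAD54B, the copies RTL8A and RTL8B, the ATXN3 retrocopy ATXN3L, the uncharacterised LOC105369669 and CORO7-PAM16 are uncertain. The cohesin subunits STAG3 and SMC1B were at -2.41 (-2.56 to -2.28) and -3.20 (-4.73 to -2.45), and the tRNA splicing subunit TSEN15 at -2.45 (-2.65 to -2.28). The number of calls depended on the depth asked for: with a count minimum of 10, 999 genes were higher and 1111 lower, and with 200 they were 265 and 383.

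**Figure D2:**
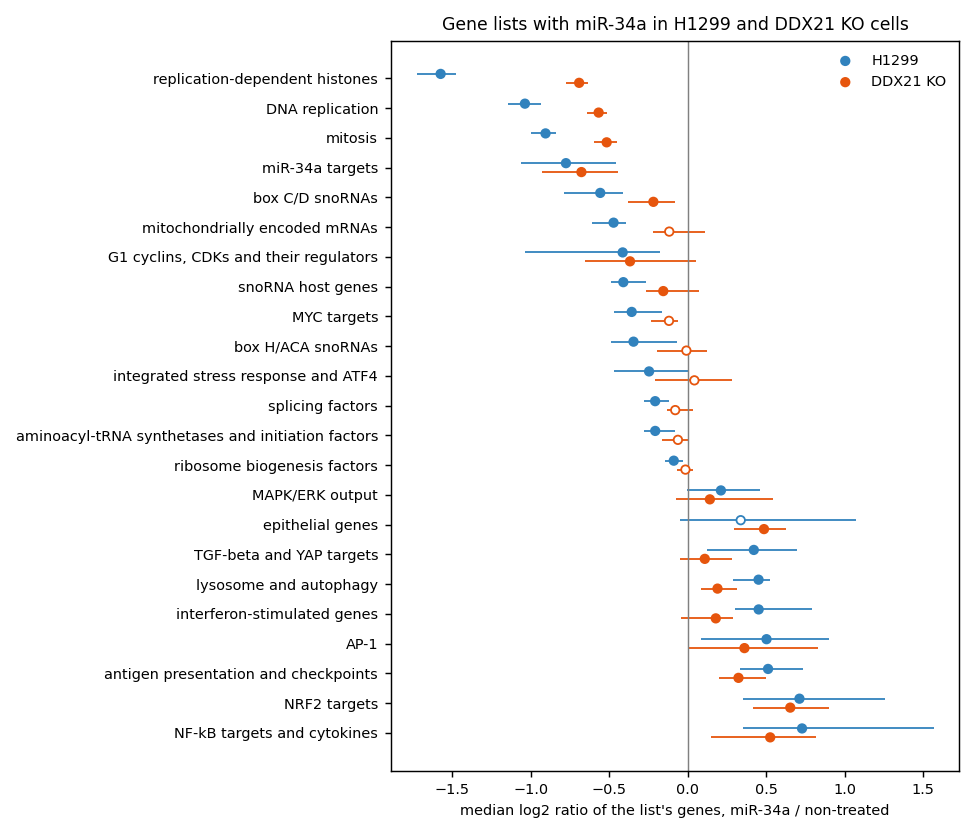
Median log2 ratio of miR-34a to non-treated cells for the lists described here that stood apart in at least 1 line (points), in H1299 and in DDX21 KO cells, with bootstrap 95% intervals over the list's genes as bars; filled points stood apart from random matched lists and open points did not. The histone list lay at -1.57 in H1299 and at -0.69 in DDX21 KO cells, and the miR-34a targets at -0.78 and -0.68.

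In DDX21 KO cells the mimic was compared in the same way, to learn which of these differences appeared when DDX21 was reduced. The same groups led, with smaller ratios for the cell cycle: miR-34a targets, histones, DNA replication and mitosis were lower, and NRF2, NF-kB and AP-1 genes were higher. Of 13382 genes entering, 217 were higher and 226 lower, 443 in all, against 276 calls among genes simulated without change at a spread between libraries of 0.2 (coefficient of variation), so spread between cultures of that size could account for some of the calls. Of 53 reported targets 16 were lower and 1 higher, with a median of -0.68 (percentile 0). AXL was at -2.05 (-2.08 to -2.03), the E2F family member E2F5 at -1.89 (-2.05 to -1.74), MET at -1.63 (-1.70 to -1.56), CDK6 at -1.48 (-1.51 to -1.45), CCNE2 at -1.36 (-1.61 to -1.13) and CDK4 at -1.19 (-1.26 to -1.12). Within 2-fold were E2F3 at -0.72, BCL2 at -0.68, SIRT1 at -0.68, CCND1 at -0.56 (-0.60 to -0.51), MYC at 0.15, NOTCH1 at 0.29 and JAG1 at 0.06, and CD274 was at 1.26 (1.00 to 1.54). The median of the histones was -0.69 with 5 of 57 lower, that of DNA replication genes -0.57 with 4 of 49 lower, that of mitotic genes -0.52 with 1 of 43 lower, and that of the G1 list -0.37 with 4 of 23 lower (each at percentile 0). TK1 was at -1.80 (-1.93 to -1.67), GINS3 at -1.46, HMMR at -1.28 and the survivin gene BIRC5 at -0.96. NRF2 targets had a median of 0.65 with 4 of 19 higher and 1 lower, among them OSGIN1 at 2.02 (1.85 to 2.21) and heme oxygenase HMOX1 at 1.59 (1.44 to 1.74). NF-kB targets had a median of 0.53 with 4 of 16 higher, LIF at 1.20 (1.01 to 1.40) and the chemokine CXCL1 at 1.13 among them. Epithelial genes (0.49), AP-1 (0.36), antigen presentation (0.32), lysosome (0.19), interferon-stimulated (0.18), MAPK/ERK output (0.14) and TGF-beta and YAP genes (0.11) stood apart on the high side, and box C/D snoRNAs (-0.22) and snoRNA host genes (-0.16) on the low side. The box C/D median was 0.07, in the other direction, with a count minimum of 200, and calls ended for snoRNA host genes (200), TGF-beta and YAP genes (10 and 200), interferon-stimulated genes (10) and, with FPKM, MAPK/ERK output genes.

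Among the 12 highest genes in DDX21 KO cells 4 were read-through loci, and ATXN3L is uncertain. ROPN1L, a radial spoke protein, was at 3.47 (2.55 to 5.88), SPEF1 at 2.68 (2.09 to 3.59), DNAH7 at 2.41 (2.00 to 2.95) and DCDC1 at 2.76 (2.00 to 4.17), with BSPRY at 3.21 (2.21 to 6.16) on 3 and 52 counts. DNAAF4, a dynein assembly factor, had 70 and 491 counts. Of the 12 lowest, 6 were read-through loci, and RTL8B has near-identical copies. The others were AXL, the lysosomal glycoprotein CD68 at -2.45 (-2.72 to -2.22), the mitochondrial enzyme ECHS1 at -2.15 (-2.27 to -2.03), MIEF1, a factor of mitochondrial fission, at -2.04 (-2.24 to -1.85), and PPFIA2, with 52 and 0 counts, at least 21.1-fold lower. CD68, ECHS1 and MIEF1 had similar ratios in H1299, at -2.29, -2.15 and -2.31. With a count minimum of 10 the calls were 618 higher and 628 lower, and with 200 they were 96 and 127.

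Genes with a match to the miR-34a seed in the 3' UTR were lower than genes without in both transfected lines. In H1299 the median log2 ratio of 2748 genes with a site minus that of 8923 genes without was -0.15 (bootstrap interval over genes -0.18 to -0.13), and in DDX21 KO cells it was -0.10 (-0.12 to -0.09) over 2768 and 8887 genes. Between the lines it was -0.0003 (-0.02 to 0.02) without treatment and 0.03 (0.01 to 0.05) with miR-34a. For genes with the 8-mer CACTGCCA the differences were -0.25 and -0.17. Of 15878 ranked 7-mers CACTGCC had the rank 9 from the most negative in H1299 and ACTGCCA the rank 4, and in DDX21 KO cells the ranks were 14 and 3 of 15893. Without treatment CACTGCC ranked 6171 of 15897 between the lines.

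**Figure D3:**
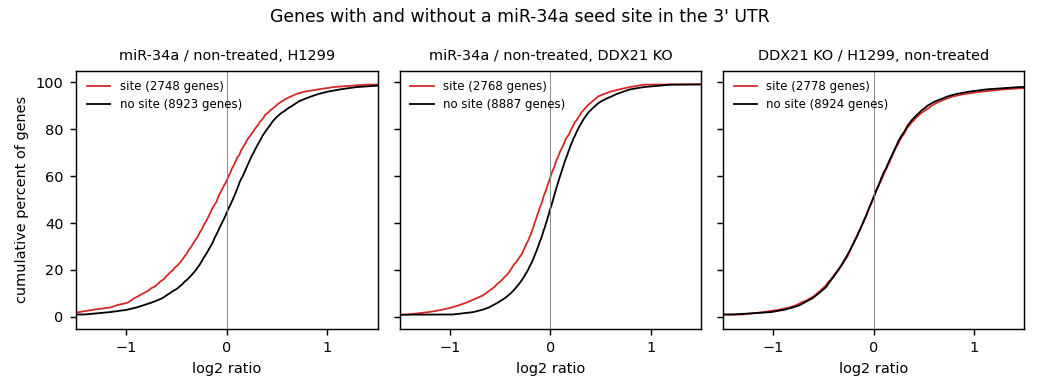
Cumulative percent of genes by log2 ratio for genes with (red) and without (black) a miR-34a seed site in the 3' UTR, in the miR-34a comparison of H1299, that of DDX21 KO cells and the comparison of the non-treated lines; the axis is limited to log2 ratios from -1.5 to 1.5. The medians differed by -0.15, -0.10 and -0.0003.

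The design then asks whether the response to miR-34a differed between the lines. Across 13015 genes that entered both comparisons, which share no library, the log2 ratios had a Pearson r of 0.65 (bootstrap interval over genes 0.60 to 0.70) and a Spearman's rho of 0.68; genes are not independent replicates. The r was 0.42 with a count minimum of 10. Both lines shared 115 higher and 136 lower genes, against 5.99 and 7.94 for independent lists, and 10 genes had calls in opposite directions. The standard deviation of the log2 ratios was 0.57 in H1299 and 0.42 in DDX21 KO cells. The difference of the ratios, DDX21 KO minus H1299, was beyond 2-fold for 586 of 13964 genes, 297 higher and 289 lower, and for 1358 and 152 genes with count minimums of 10 and 200. It was highest among the lists for the histones, with a median of 0.88 (percentile 100) and 16 of 57 beyond 2-fold, and for DNA replication (0.46), mitosis (0.37), mitochondrially encoded mRNAs (0.41) and ATF4 targets (0.28). Single values were 1.36 for H4C9, 1.19 (1.07 to 1.31) for TYMS, 0.84 for GINS1, 0.81 for the anaphase activator CDC20 and 0.73 for FOXM1. MYC targets (0.15), snoRNA host genes (0.21), splicing factors (0.13), MAPK/ERK output genes (0.13), miR-34a targets (0.10) and ribosome biogenesis factors (0.07) also stood apart on the high side. The bootstrap intervals over genes of the miR-34a target median (-0.08 to 0.22) and the MAPK/ERK output median (-0.14 to 0.32) included no change. Splicing factors, ribosome biogenesis factors, MYC targets and mitochondrially encoded mRNAs stood apart only in ratios that use the non-treated H1299 library, as this difference does. ATF4 targets stood apart only in ratios that use the miR-34a H1299 library, which this difference uses too. On the low side were interferon-stimulated genes with a median of -0.32 (percentile 0), epithelial genes (-0.31), NF-kB targets (-0.22), lysosome genes (-0.20), antigen presentation genes (-0.15) and nuclear OXPHOS subunits (-0.13). IFI44 differed by -3.38 (-4.28 to -2.48), LGALS3BP by -1.45 (-2.06 to -0.84) and LIF by -1.32 (-1.67 to -0.97). The epithelial median had the other sign with a count minimum of 200 and with FPKM, where MAPK/ERK output and antigen presentation genes no longer stood apart either, nor did miR-34a targets with FPKM. CDK4 differed by 0.47 (0.36 to 0.57), MET by 0.24 (0.13 to 0.34), AXL by 0.18 (0.14 to 0.22), CDK6 by -0.27 (-0.31 to -0.22) and CCND1 by -0.36 (-0.41 to -0.30). Of the 6 highest and 6 lowest single genes, 9 were read-through loci and ATXN3L and LOC105369669 are uncertain as well. The remaining gene, FCHO1, a factor of endocytic pits, had 152 and 43 counts in H1299 and 0 and 13 in DDX21 KO cells. Its difference was 3.49 against the floor of 3 counts and 4.45 (2.27 to 6.63) with the prior count of 2.

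The lines themselves were compared first without treatment. The medians of mesenchymal genes, epithelial genes and targets of TGF-beta and YAP were higher in DDX21 KO cells, while that of mitochondrially encoded mRNAs was lower. Of 13600 genes 516 were higher and 374 lower. Mesenchymal genes had a median of 0.78 (percentile 100) with 5 of 15 higher; SNAI2, a repressor of epithelial genes, was at 3.70 (2.88 to 6.24) and the matrix protease MMP2 at 3.63 (3.10 to 4.54), against -0.76 for ZEB2 and -0.67 for CDH2. The bootstrap interval over genes of the mesenchymal median, -0.25 to 1.12, included no change. With a count minimum of 200 the median was 0.23 and no longer stood apart. Epithelial genes had a median of 1.07 (percentile 100) with 4 of 7 higher and 1 lower, KRT7 at 1.84 (1.23 to 2.72) and desmoplakin DSP at 1.53 (1.35 to 1.73), and OCLN, the lower one, at -1.15. Of TGF-beta and YAP targets 6 of 24 were higher (median 0.54), TGFBI at 2.08 (1.98 to 2.18) and PMEPA1 at 1.55. Lysosome genes (0.27), NRF2 targets (0.23) and Wnt pathway genes (0.18) also stood apart on the high side. The 13 mitochondrially encoded mRNAs had a median of -0.69 (percentile 0), with ND3 at -1.18 and CYTB at -1.06, and the non-treated H1299 library also had the highest share of counts on rRNA genes, 0.663% against 0.346% to 0.467% in the others. Groups close to the function of DDX21 differed little: ribosome biogenesis factors had a median of -0.12 (percentile 0.6) with 0 of 90 beyond 2-fold, cytosolic ribosomal proteins -0.12 (percentile 1.5), and RNA polymerase I factors -0.06 (percentile 29.1). DEAD-box helicases were at -0.21 (percentile 0.3), and DDX21 was the 1 member of 36 that was lower. Cholesterol synthesis (-0.28), miRNA machinery (-0.26), histones (-0.21), splicing factors (-0.20), DNA replication (-0.17) and both snoRNA classes (-0.32 for box C/D and -0.31 for box H/ACA) were also low. Mitochondrially encoded mRNAs, splicing factors, box H/ACA snoRNAs and ribosome biogenesis factors stood apart only in ratios that use the non-treated H1299 library. DEAD-box helicases, cholesterol synthesis and miRNA machinery genes stood apart in this comparison alone, which uses that library as well. The low medians of all these lists here cannot be told apart from a deviation of that library. The box C/D median was 0.16, in the other direction, with a count minimum of 200, and calls ended for box H/ACA snoRNAs with minimums of 10 and 200 and with 20 bins, and for Wnt genes with a minimum of 200 and with FPKM.

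The genes that differed most between the non-treated lines were near or at 0 in 1 of them. BACE2 (gene 25825, chromosome 21, 41168160 to 41282530), a protease, had 0 counts in non-treated H1299 and 204 in DDX21 KO cells, at least 90.2-fold higher against the floor. NNMT, a nicotinamide methyltransferase, was at least 58.3-fold higher, the TGF-beta pseudoreceptor BAMBI and LZTS1 at least 48.2-fold each, the potassium channel subunit KCNS3 at least 46.0-fold and the matrix protein MFAP5 at least 37.1-fold. The transcription factor FOXF1 had 0 and 77 counts. NLRP4 and ANO2 were at least 34.9-fold and 34.5-fold higher. The semaphorin receptor NRP1 had 20 and 764 counts, a log2 ratio of 5.51 (5.03 to 6.38), and the GABA receptor subunit GABRG1 was at 5.64 (4.88 to 8.73) on 3 and 197 counts. In the other direction ADGRB3 had 175 and 0 counts, at least 44.0-fold lower in DDX21 KO cells, FCHO1 was at least 38.2-fold lower, SLC35F1 at least 35.7-fold, the CTCF paralog CTCFL at least 30.7-fold, CNTF at least 25.6-fold, PTCHD1 at least 20.6-fold, TMEM88 at least 19.6-fold, PDGFD at least 18.9-fold, COL11A1 at least 17.6-fold and GFRA1 at least 15.8-fold. ZNF704 had 597 and 21 counts and a log2 ratio of -4.31 (-5.13 to -3.80). ATXN3L, at 118 and 0 counts, is uncertain. With a count minimum of 10 the calls were 1191 higher and 885 lower, and with 200 they were 216 and 160.

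With miR-34a in both lines, 544 genes were higher and 403 lower in DDX21 KO cells, of 13621. The mesenchymal median was again higher (0.96, percentile 100, 7 of 15 higher and 1 lower), with MMP2 at 3.51 (2.88 to 4.64) and SNAI2 at 2.43 (1.72 to 3.63), and LOX at -1.46 (-1.75 to -1.20). Its bootstrap interval over genes, -0.06 to 1.55, included no change, and with a count minimum of 200 the median was 0.19 and did not stand apart. Epithelial genes (0.63), TGF-beta and YAP targets (0.41), Wnt genes (0.28), receptor tyrosine kinases (0.30) and NRF2 targets (0.19) stood apart on the high side, and ROR2, a Wnt receptor, was at least 22.1-fold higher. So did the histones at 0.63 (percentile 100), DNA replication at 0.31 and mitosis at 0.30, which without miR-34a had medians of -0.21, -0.17 and -0.04. Targets of ATF4 had a median of 0.45 (percentile 100), with GDF15 at 2.30 (1.75 to 3.11) and NUPR1 at 3.13. This list stood apart only in ratios that use the miR-34a H1299 library. Its median therefore cannot be told apart from a deviation of that library. NF-kB targets (-0.29) and ribosomal proteins (-0.16) stood apart on the low side, the former no longer with a count minimum of 10, and mitochondrially encoded mRNAs, at -0.29 (percentile 2.83, 0 of 12 called), did not. Of the 12 highest genes BACE2, MFAP5, BAMBI, KCNS3, FOXF1, NRP1 and NNMT were among the 12 highest without miR-34a too, and ATXN3L, with 0 and 107 counts, is uncertain. BACE2 was at least 62.5-fold higher, MFAP5 at least 56.9-fold, BAMBI at least 55.9-fold, the scavenger receptor COLEC12 at least 51.5-fold, ADORA2A at least 35.1-fold and UNC5B at least 32.1-fold, and PREX1 was at 5.22 (4.45 to 7.33). COLEC12 and ADORA2A had 40 and 26 counts in non-treated H1299, so their folds rest on the 0 in the miR-34a H1299 library. Of the 12 lowest 3 were read-through loci. DNAJC15, a mitochondrial co-chaperone, had 170 and 0 counts, at least 56.5-fold lower, CNTF was at least 36.9-fold lower, S100A16 at least 25.6-fold, KLHL32 at least 20.3-fold and TMEM88 at least 19.6-fold. KLHL32 had 17 counts in non-treated DDX21 KO cells, so its fold rests on the 0 in the miR-34a DDX21 KO library. ADGRB3, with 135 and 2 counts, had a log2 ratio of -5.09 (-9.13 to -4.19), PDGFD one of -4.79 (-7.80 to -3.93) and ARHGAP4 one of -4.68 (-5.80 to -4.09). With a count minimum of 10 the calls were 1257 higher and 933 lower, and with 200 they were 215 and 172.

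The comparisons of the lines without and with miR-34a share no library, and their log2 ratios correlated across 13257 genes with a Pearson r of 0.75 (bootstrap interval over genes 0.71 to 0.78) and a Spearman's rho of 0.66. They shared 304 higher and 155 lower genes, against 16.7 and 7.81 for independent lists, and 8 genes had opposite calls.

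**Figure D4:**
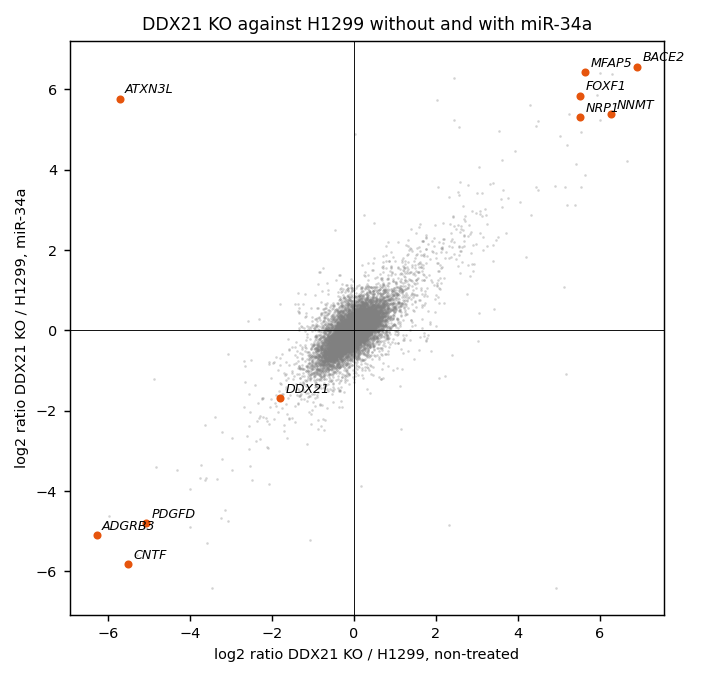
Log2 ratio of DDX21 KO to H1299 without miR-34a (x) and with miR-34a (y) for 13257 genes (grey points), with 10 named genes marked in orange; ratios against a library with 0 counts depend on the prior count of 2. The ratios correlated with r = 0.75, and ATXN3L lay at -5.72 and 5.77.

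Some lists stood apart in none of the 5 sets of ratios (the 4 comparisons and the difference): BCL2 family genes, 7SK and P-TEFb genes, the Notch pathway, the unfolded protein response, heat shock genes and hypoxia and glycolysis genes had medians between -0.10 and 0.16. Of the cell type markers, 0 of 15 for alveolar and airway epithelium and 0 of 10 for fibroblasts reached 50 reads in any library. Neuroendocrine markers gave 6 of 14 in at least 1 library, UCHL1 with the highest level among them, and their medians of 0.28, -0.09, 0.38 and 0.18 in the 4 comparisons did not stand apart. Fewer passed among the rest, with blood and immune markers 2 of 12 (CD68 and ITGAM), and endothelial markers 1 of 9 (KDR). KDR was higher in DDX21 KO than in H1299 cells, with log2 ratios of 2.49 (1.93 to 3.34) and 1.77 (1.37 to 2.28).

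The authors' deposited table lists 908 genes with a fold of at least 2 and a raw p under 0.05 in at least 1 comparison. According to the authors' deposited table, 331 genes passed both limits for miR-34a in H1299, 105 for miR-34a in DDX21 KO cells, 393 for the non-treated lines and 409 for the lines with miR-34a. After adjustment, the authors' deposited table holds 0, 1, 10 and 11 genes with an adjusted p under 0.05 in the same order. The authors' deposited table gives NRP1 a signed fold of 50.2 without and 44.4 with miR-34a, both among the adjusted calls, and DDX21 signed folds of -3.52 and -3.16, with an adjusted p of 1.00 for both. Of its genes with at least 50 reads here, 218 of 218, 61 of 61, 271 of 271 and 286 of 286 had the same direction, which is not independent since both rest on the same counts. Among gene ontology terms, the authors' deposited table puts nucleosome first among cellular components, with 27 of 111 genes and an adjusted p of 7.55e-14.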

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

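The tests of these patterns were chosen after the result was seen, except the ratio of seed-site shifts and the overlap and on-off tests of the lines.

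Differences in direction between the lines, which were not tested, stood out for 3 named genes that were called at least 2-fold in opposite directions by miR-34a. ATXN3L had 118 and 0 counts in H1299 and 0 and 107 in DDX21 KO cells. Its difference of the log2 ratios was 10.05 against the floor of 3 counts and 11.49 (8.63 to 14.34) with the prior count of 2, and neither value is a bound. MICOS10-NBL1 had 0 and 340 counts in H1299 and 51 and 2 in DDX21 KO cells. Its difference was -10.88 against the floor and -11.42 (-13.90 to -8.93) with the prior count. FMC1-LUC7L2 had 624 and 276 counts in H1299 and 180 and 523 in DDX21 KO cells, a difference of 2.30. ATXN3L is a retrocopy of ATXN3, and both others are read-through loci that share exons with their neighbours, so the values of all 3 are uncertain. Each difference kept its sign with the alternative scalings, but the sizes for ATXN3L and MICOS10-NBL1 moved beyond the counting interval with a prior count of 0.5, where they were larger, and with the deposited FPKM, where they were much smaller.

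The lower level of cell cycle genes with miR-34a was smaller in DDX21 KO cells. The median of the histones was -0.69 there and -1.57 in H1299, 0.439 of it, and the ratio was 0.547 for DNA replication and 0.570 for mitosis, against 0.873 for reported miR-34a targets. These are ratios of medians, given without intervals. Ratios over all genes that entered both comparisons also spread less in DDX21 KO cells, with a standard deviation of 0.42 against 0.57 in H1299. The target list also holds cell cycle genes such as CDK4 and CCNE2. Its per-gene difference went in the same direction, with a median of 0.10 (percentile 99.3). The bootstrap interval over genes of that median, -0.08 to 0.22, included no change, and 31 members lay above 0 and 22 below. With FPKM the list no longer stood apart. Histone mRNAs are short, but the cytosolic ribosomal protein mRNAs, also short, differed between the lines by -0.034 (bootstrap interval over genes -0.050 to -0.014), which argues against a general difference in recovery of short transcripts; this test replaced one on library scaling, which was void, and one on structural RNAs such as RN7SK, whose difference was -0.12. The comparison of the transfected libraries does not use the non-treated H1299 library and put the histones at 0.632 (percentile 100). That value argues against a misplaced non-treated H1299 library as the only difference between the libraries. It cannot exclude such a library together with a constant difference between the lines, which would give the same values, so this stays open. The transfected libraries have no such check. Less miR-34a activity in the transfected DDX21 KO cells, from uptake or dose, stays open: the seed-site shift there was 0.672 of that in H1299 (bootstrap interval over genes 0.595 to 0.778), between the bounds set beforehand, and an effect of DDX21 loss on the response remains open and untested, since each line was transfected in 1 library.

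The genes that differed between the lines were often shared without and with miR-34a. Shared calls of the same direction numbered 459 against 24.5 for independent lists, 18.7 times as many, which argues against count noise of genes with few reads. Descent of the DDX21 KO line from a single cell, which would fix the on or off state of genes by chance, and loss of DDX21 cannot be told apart with 1 knockout line: 10 protein-coding genes had at least 50 reads in both DDX21 KO libraries and at most 3 in both H1299 libraries, and 6 the reverse, ADGRB3, CNTF, PDGFD, TMEM88 and SLC35F1 among them. Whether the line is a clone is not given in the sources used here, so either origin could account for BACE2, BAMBI or FOXF1.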

How the results depend on the processing

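No alternative was added after the results were seen. No paired analysis was possible within a comparison because each held 1 library per group; an additive fit across all 4 libraries with the line as a block, which would take its residual from the difference between the lines, was not run. Scaling by DESeq2 size factors or total counts, a prior count of 0.5 and protein-coding genes alone left every count of calls within 1.5 times its value, except that the difference was higher for 193 genes with protein-coding genes alone, which tests fewer genes, and for 297 in the main setting. The counts below are given for miR-34a in H1299, miR-34a in DDX21 KO cells, the non-treated lines, the lines with miR-34a, each higher and lower, and the difference beyond 2-fold. A count minimum of 10, which admits more genes with few reads, gave 999 and 1111, 618 and 628, 1191 and 885, 1257 and 933, and 1358. A minimum of 200, which tests fewer genes, gave 265 and 383, 96 and 127, 216 and 160, 215 and 172, and 152. The deposited FPKM, with a pseudocount of 0.5, gave 235 and 357, 101 and 119, 255 and 148, 252 and 154, and 192. These calls used the fold threshold alone, without an interval. Scale, added constant and rule changed together, so the cause of the lower counts was not tested. A threshold of 1.5-fold, looser by construction, gave 1443 and 1756, 798 and 910, 1246 and 1341, 1341 and 1343, and 1534.

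The correlation of the miR-34a ratios between the lines was 0.42 at a minimum of 10, 0.79 at 200 and 0.70 with FPKM, and that of the ratios between lines without and with miR-34a was 0.62 at 10, 0.70 with FPKM and 0.66 by Spearman's rho. The cause of these differences was not tested. The seed-site shift was -0.25 in H1299 and -0.17 in DDX21 KO cells with 8-mers alone and kept its sign under each alternative. Of the medians of lists that stood apart, taken under each alternative, 481 kept their direction and stood apart, 85 of them with DESeq2 size factors and 85 with total counts, while 24 no longer stood apart, each named beside its value in the report, and 5 changed sign: box C/D snoRNAs at a minimum of 200, where few of them enter, at 0.15 and 0.071 with miR-34a in H1299 and DDX21 KO cells and 0.16 between the non-treated lines, and the difference of the epithelial genes, 0.081 at 200 and 0.0225 with FPKM. The cause of the last was not tested. Of the values of named genes 502 lay within the counting interval and 106 beyond it, 103 of these with FPKM and 3 with the prior count of 0.5, and none that was called changed sign.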

Other observations

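The axoneme gene families, the test of airway cells and the other genes named here were chosen after the result was seen. The bounds of the test of count noise were written before its outcome, but it uses these families, so it is not independent of the result.

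Genes of the motile cilium were higher with miR-34a in both lines. The gene families that make the axoneme (DNAH, DNAI, DNAL, DNAAF, CFAP, RSPH, TEKT, DRC and ODAD, as current or former symbols) had a median log2 ratio of 0.67 in H1299, with 19 of 49 higher and 0 lower, and of 0.71 in DDX21 KO cells, with 17 of 48 higher and 0 lower (percentile 100 in each), while the difference of the ratios per gene, DDX21 KO minus H1299, had a median of -0.15 (percentile 1.2) over 51 genes, 35 of them below 0. Of these genes 47 of 49 and 43 of 48 had a ratio above 0. In the comparison of the non-treated lines 40 of the families' genes entered. Others entered through a transfected library alone, which favours ratios above 0 and a higher median. Between the non-treated lines the median was 0.06 (percentile 83.9), and with miR-34a it was -0.18 (percentile 1.2) in DDX21 KO against H1299. FOXJ1, the main transcription factor of motile cilia and 1 of the airway markers, had 0 counts in both non-treated libraries and 12 and 4 in the transfected ones, too few to enter. CCP110, a centriole cap protein that holds back cilium assembly and is a reported target of the miR-34 and miR-449 family, was at 62.5 and 79.7 CPM in H1299 and at 52.5 and 76.4 in DDX21 KO cells, higher with miR-34a.

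Count noise of genes with few reads is argued against by the families without the genes named in the report, whose median was 0.653 in the DDX21 KO pair and 0.51 in the H1299 pair (percentile 100 in both), since these pairs share no library. Airway epithelial cells in the transfected cultures are argued against as well: 0 of the 15 alveolar and airway markers reached 50 reads in a transfected library, the highest being AGER with 13 reads, and SCGB1A1, SFTPC and MUC5B had 0. That miR-34a, or the transfection, raises axoneme genes in these cells is therefore a hypothesis from these data, and the design cannot separate the 2 because no control RNA is named. A slower cell cycle is another possible explanation that was not tested separately.

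Several other genes called in opposite directions by miR-34a in both lines lie outside the rule for named genes. ZNF117 had 115 and 294 counts in H1299 and 720 and 244 in DDX21 KO cells, and its read-through partner ERV3-1-ZNF117 had 596 and 626 in H1299 and 88 and 760 in DDX21 KO cells. ZNF117 shares exons with this read-through locus, so the assignment of reads between them and its opposite calls are uncertain. LRP2BP had 56 and 13 counts in H1299 and 30 and 83 in DDX21 KO cells. The abundant structural RNAs RN7SL1, RN7SL2, RN7SK, RMRP and RPPH1 had log2 ratios with miR-34a between 0.21 and 0.46 in H1299 and between 0.06 and 0.40 in DDX21 KO cells.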
